A study of Mus musculus with 2 samples.

How the data were processed

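Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on the mouse embryonic stem cell line E14Tg2a with an antibody to acetylated histone H3 lysine K56 (H3K56ac), a residue in the globular core of H3 near the entry and exit points of the nucleosomal DNA. The labels give 2 libraries, 1 of H3K56ac ChIP and 1 of input DNA, with 1 library per group. The deposited interval list of the ChIP library was analysed; the input library was not analysed here. Per the labels' protocols, cells grown in serum and leukaemia inhibitory factor were fixed with formaldehyde, sheared by sonication and sequenced on an Illumina instrument after library amplification.

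Per the submitters' processing notes, the genome build was mm9 and Bowtie was used; its version, the program that called the intervals, its threshold, the way in which the input library entered the calls and any joining of windows are not given in the sources used here. The deposited list has no header and 3 columns, which hold a chromosome name, a start and an end in base pairs. It holds no read counts, heights, scores or p-values, so that depth is unknown, no interval can be ranked by strength, and width is the only graded property of an interval. Tested on the file, 0 starts and 0 ends were off a grid of 50 bp steps when starts were counted from 1 with the end included, and positions are given in that form. Neighbouring intervals never overlapped, and the smallest gap was 150 bp. On 9 of 20 chromosomes, 895 intervals in all lay past the last gene of the RefSeq gene table of assembly GRCm38.p6, and the build named in the notes also differs from that assembly, so its coordinates were not used for the list. Chromosome lengths were not compared. No mm9 genome or annotation was used here and no coordinate was converted, so intervals carry no gene names, and 7 results planned before the data were examined were not computed: intervals at transcription start sites, intervals by genomic feature, genes with an interval at the start, the fixed gene lists, the Oct4 motif, GC content and an interval score.

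Densities were computed as intervals per Mb between the first and the last interval of each chromosome, because chromosome lengths of mm9 were not used here. Exact Poisson intervals (95%) cover counting error only and treat intervals as independent, which clustered intervals are not. Ratios between chromosomes therefore carry 95% intervals from 2000 resamplings of 5 Mb blocks (491 autosomal and 33 X blocks), with a fixed seed. Spacing was compared with 100 random placements of the same intervals on the same chromosomes, on the 50 bp grid, without overlap and with gaps of at least 150 bp, from position 1 to the end of the last interval. Unmappable stretches were not excluded from the placements. Clusters were formed by joining intervals less than 12.5 kb apart, a distance in common use for joining enhancers into larger domains. This clustering, the bins of 1 Mb, the count of gaps by 50 bp steps, the reassignment of 5 Mb blocks among the autosomes (1000 times) and the test of distal chromosome ends were chosen after the data were examined; the number and width of intervals, the density per chromosome and the spacing were fixed before. By the rule fixed beforehand for a list without annotation or score, the 5 longest intervals are named by position. With 1 library there is no biological or technical replicate: all errors describe the placement of intervals within this list, and no difference between conditions was tested.

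The code was tested on simulated data. For spacing, an unclustered list of 92549 intervals gave a ratio of random to observed median gap of 1.01 where 1 was set. That list came from the same placement procedure, so this checks the code and not the random model. For clusters, 1000 of 1000 built clusters were recovered from 5000 intervals. For the density ratio, a set value of 2.5 was recovered as 2.50 over 40 unclustered lists of on average 91369 intervals and as 2.52 over 40 clustered lists of on average 91335 intervals, and the block interval held the set value in 95% of each. The clustered lists held clusters of 10 intervals placed independently of one another. Counts in the deposited list were correlated between neighbouring megabases, which was not simulated, so this coverage need not hold for that list. Alternatives were merging intervals less than 500 or 1000 bp apart, keeping intervals wider than the median, counting bases instead of intervals, other limits for the random placements and, added after the data were examined, leaving out the sequence named 21, other lengths, other cluster distances and other bin sizes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.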

Results

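To describe where H3K56ac lies in the genome of mouse embryonic stem cells, the interval list of a single H3K56ac ChIP-seq library from E14Tg2a cells was examined. E14Tg2a is a widely used feeder-independent line derived from the mouse inner cell mass. The question named by the study is the relation of H3K56ac to Oct4, the transcription factor that maintains pluripotency; the list locates H3K56ac alone, and Oct4 binding was not analysed here. The list held 92549 intervals on 19 autosomes, X and a sequence named 21. The number of reads behind them is unknown, and the values below come from 1 library without a replicate.

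Most H3K56ac intervals of the list were short, and few were broad. The median interval width was 100 bp, with quartiles of 50 and 200 bp, a mean of 182 bp and a maximum of 7250 bp. Intervals of 50 bp numbered 28385 (30.7% of the list) and those of 100 bp numbered 25466 (27.5%). The 1439 intervals of 1000 bp or more made up 1.55% of the list and held 12.7% of its bases. All intervals together covered 16.9 Mb, which was 0.655% of the 2574 Mb between the first and last intervals of the chromosomes. Most intervals were thus narrower than the DNA wrapped around 1 nucleosome, at the 50 bp resolution of the list. No gap was under 150 bp on the 50 bp grid, as joining of closer windows would give. The calling threshold and the rule for any such joining are unknown, so interval width cannot be read as the size of an acetylated site. Short sites were not told apart from pieces of broader ones or from false calls.

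The 5 longest intervals lay on chromosomes 18, 5, 4 and 9, in the mm9 coordinates named by the submitters' processing notes. The longest, 7250 bp on chromosome 18 from 61790501 to 61797750, belonged to a cluster of 19 intervals with 17500 bp of interval sequence. The second was 4550 bp long on chromosome 5, from 118884351 to 118888900, in a cluster of 49 intervals. An interval on chromosome 4 (141725851 to 141730150) and another on chromosome 9 (58120301 to 58124600) were both 4300 bp long, in clusters of 14 and 51 intervals. The fifth, 4150 bp on chromosome 18 from 38791451 to 38795600, lay in a cluster of 86 intervals that together covered 30000 bp. None of the 5 stood alone, but only 9602 of the 92549 intervals of the list did. Their gene context was not analysed here.

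The density of H3K56ac intervals differed between chromosomes. Chromosome 11 was the densest, with 61.4 intervals per Mb (exact Poisson 95% interval 60.0 to 62.8), followed by chromosome 17 with 51.3 (49.8 to 52.7) and chromosome 19 with 48.5 (46.7 to 50.3). Chromosome 3 had the lowest autosomal density, 24.2 intervals per Mb (23.4 to 24.9), below chromosome 13 with 25.6 (24.7 to 26.6) and chromosome 14 with 26.2 (25.3 to 27.1). The mean over the 19 autosomes was 38.0 ± 9.91 intervals per Mb (SD between chromosomes). Chromosome 11 exceeded chromosome 3 by 2.54-fold (95% interval 1.60 to 4.06 from resampled 5 Mb blocks), an interval that does not allow for their choice as the highest and the lowest of 19. When 5 Mb blocks were reassigned at random among the autosomes, the highest exceeded the lowest by 2.16-fold on average and by at least the observed ratio in 145 of 1000 reassignments (one-sided permutation p = 0.15). The SD between autosomes was 7.30 on average in these reassignments and reached 9.91 in 23 of 1000 (one-sided permutation p = 0.024). The reassignments treat blocks as independent, although counts were correlated between neighbouring megabases, so both p-values may be too small. Neither was adjusted for the other. The 1.20-fold difference between chromosomes 11 and 17 had a block interval of 0.710 to 2.12 and could not be told from the unevenness along each chromosome.

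The X chromosome carried fewer H3K56ac intervals than every autosome, and their mean width was lower. It had 2202 intervals, or 13.5 per Mb (12.9 to 14.1), against 37.5 per Mb over the pooled autosomes, a 2.78-fold difference (block 95% interval 2.09 to 3.94). Counted in interval bases, the autosomes had 6877 bp per Mb and X 1846 bp per Mb, a 3.73-fold difference (2.76 to 5.38). E14Tg2a is a male line with 1 copy of X, and neither difference was corrected for copy number. Fewer called intervals on X can therefore not be read as less H3K56ac per copy. The mean width was 137 bp on X, while the autosomes ranged from 164 bp on chromosome 13 to 200 bp on chromosome 18 and averaged 184 ± 10.0 bp (SD, 19 autosomes). The median width did not differ: it was 100 bp on X and on each of the 19 autosomes. Intervals of 1000 bp or more were 5 of the 2202 on X, 0.227%, against 0.905% to 2.27% on the autosomes. The difference was larger for wide intervals: those of at least 500 bp were 6.20-fold denser on the autosomes (4.04 to 11.3), whereas clusters of joined intervals were 1.71-fold denser (1.41 to 2.17). Joining at a fixed distance merges more intervals where they are denser, which in itself tends to lower the ratio for clusters. The sequence named 21 held 106 intervals between 48451 and 2895950, with a mean width of 91.5 bp and none of 1000 bp or more.

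**Figure D1:**
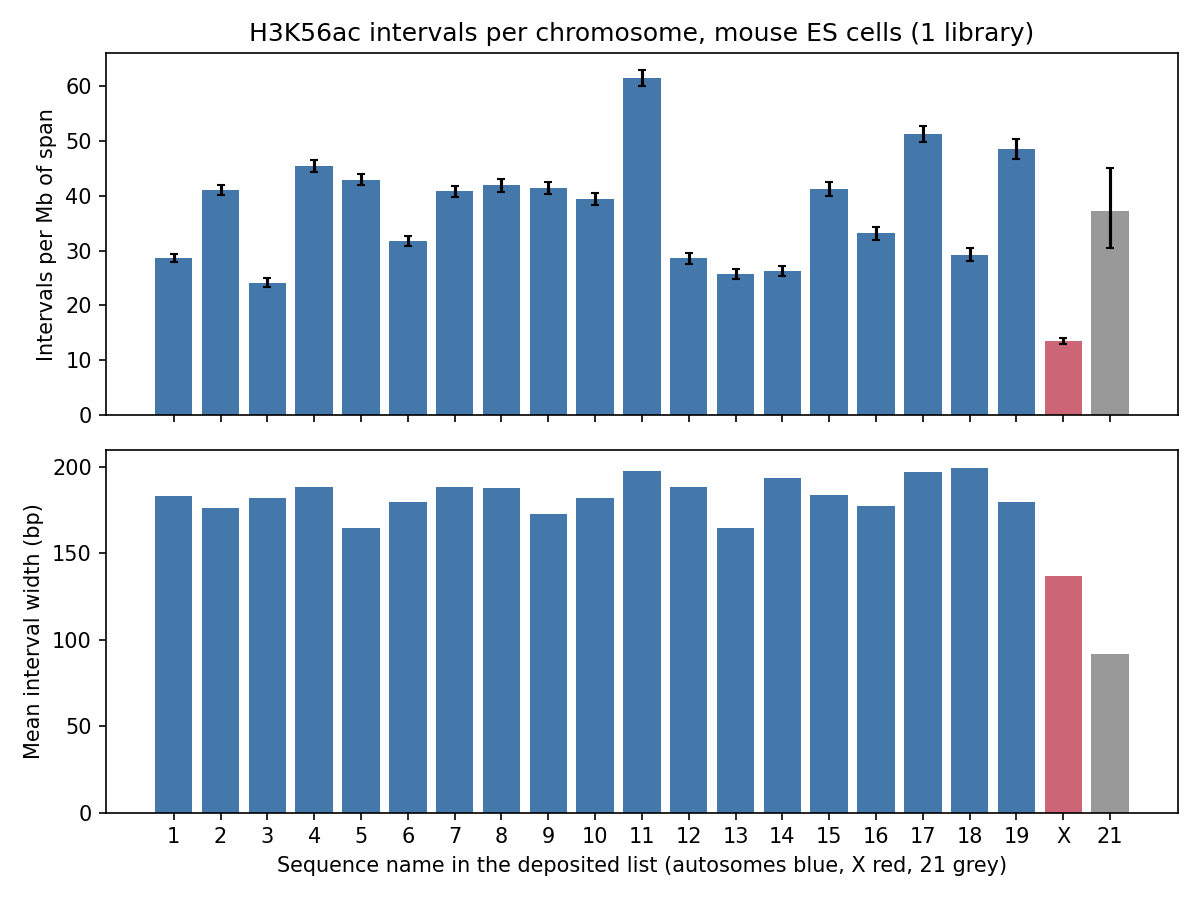
Intervals per Mb of span (upper panel; bars with exact Poisson 95% intervals, which cover counting error only) and mean interval width in bp (lower panel) for each sequence of the list, autosomes in blue, X in red and the sequence named 21 in grey. X had the lowest density, 13.5 per Mb, and its mean width of 137 bp lay below that of all 19 autosomes.

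H3K56ac intervals were strongly clustered along the chromosomes. The median gap between neighbours was 1550 bp (quartiles 450 and 11500 bp), whereas the same intervals placed at random had a median gap of 18501 bp on average (18350 to 18650 bp over 100 placements), 11.9 times the observed value. A neighbour lay less than 1 kb away for 61.6% of intervals, against 6.18% (5.90% to 6.51%) in the random placements. Wider intervals were closer to others. A neighbour within 1 kb was present for 43.8% of the 50 bp intervals, 57.1% of the 100 bp intervals, 74.5% of those of 150 to 450 bp, 91.7% of those of 500 to 950 bp and 97.5% of those of 1000 bp or more. In the random placements the means for these classes lay between 6.12% and 6.31%. Merging intervals less than 500 bp apart reduced the ratio of random to observed median gap to 5.63. Pieces of a broader site would also lie close together and were not told apart from separate sites. The clustering is therefore that of called intervals, relative to uniform random placement.

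**Figure D2:**
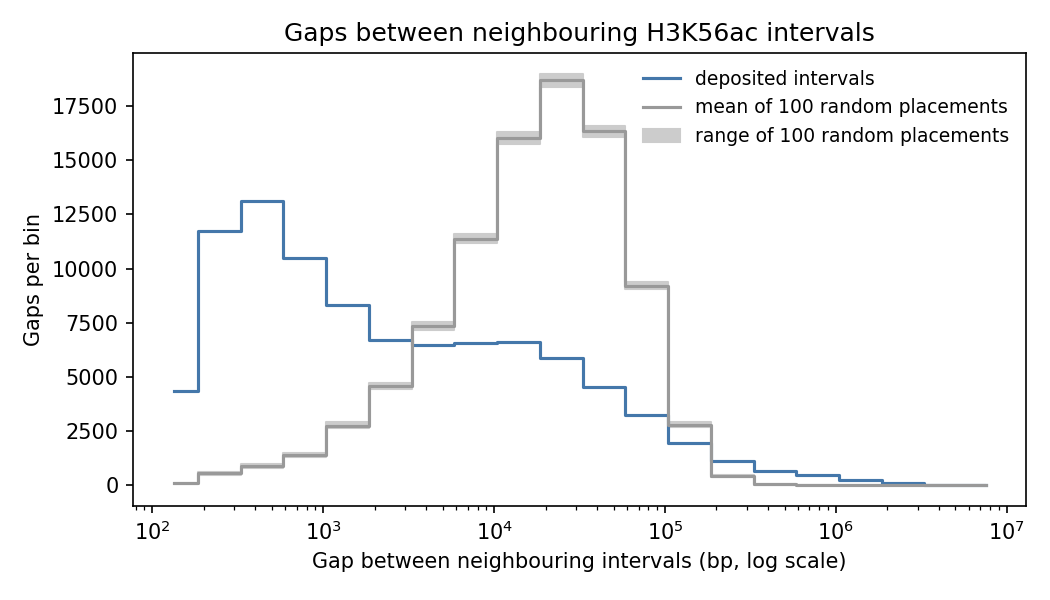
Number of gaps between neighbouring intervals (vertical axis) by gap length in bp (log axis) for the deposited list (blue) and for 100 random placements (grey line, mean; grey band, lowest to highest). The observed gaps, with a median of 1550 bp, lie to the left of the random ones, with a mean median of 18501 bp, and also extend to longer gaps than any random placement gave.

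At short range, gap lengths did not decline evenly. Gaps of exactly 300 bp numbered 4478, more than gaps of 250 bp (3784) or of 350 bp (3146). Relative to a log-linear trend fitted to gaps of 400 to 1000 bp, the count at 300 bp was 1.27 times the trend (95% counting interval 1.23 to 1.31), that at 250 bp 0.966 times (0.935 to 0.997) and that at 350 bp 0.991 times (0.957 to 1.03). At 400 bp the count was 1.04 times the trend (1.01 to 1.08). Gaps of 200 bp were fewer than the trend (0.795 times, 0.768 to 0.822). The count at 300 bp exceeded the counts at both 250 and 350 bp on 17 of 20 chromosomes (autosomes and X). The ratio of the 300 bp count to the mean of those at 250 and 350 bp was 1.33 for neighbours that were both 50 or 100 bp wide, 1.27 for neighbours both of 150 bp or more, and 1.30 for mixed pairs.

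**Figure D3:**
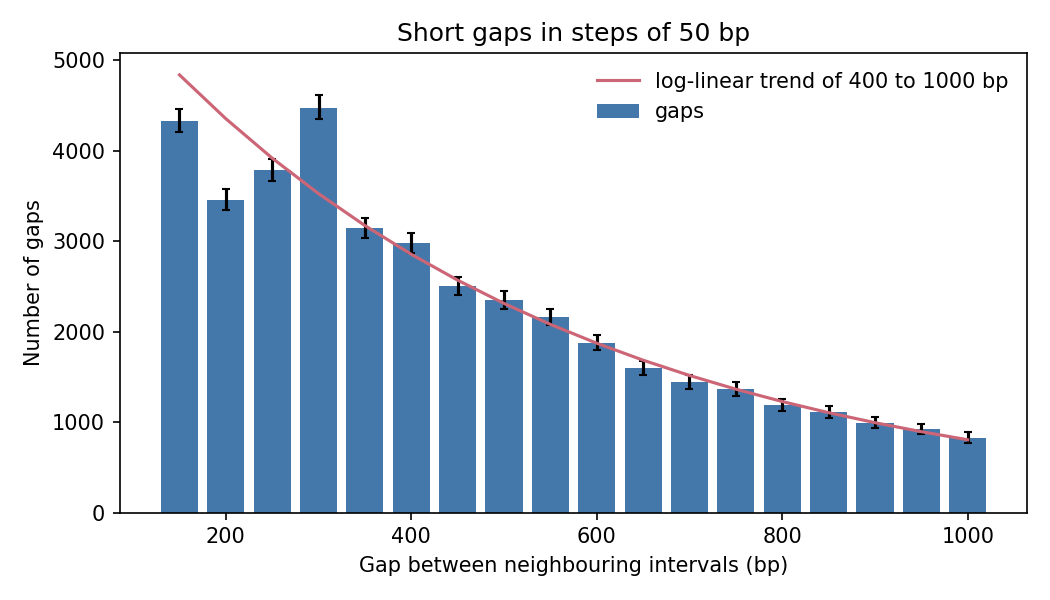
Number of gaps between neighbouring intervals at each gap length from 150 to 1000 bp in steps of 50 bp (bars with exact Poisson 95% intervals) and the log-linear trend of gaps from 400 to 1000 bp (red line). The bar at 300 bp, 4478 gaps, stands above the trend, and the bars at 250 and 350 bp do not.

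Joined into clusters, the intervals formed 22232 clusters, against 57886 on average in the random placements (57604 to 58235). Clusters of a single interval numbered 9602 (43.2%), and 2091 clusters had 10 or more intervals, where the random placements had 15 to 33. The top 1% of clusters by interval bases (222 clusters) held 20.3% of all interval bases, and the top 10% (2223 clusters) held 62.1%. The cluster with the most interval bases lay on chromosome 12 from 88109201 to 88289150, where 130 intervals covered 66.5 kb (36.9%) of 180 kb. The next were on chromosome 8 from 122827901 to 123097800, with 174 intervals covering 49.3 kb, and on chromosome 11 from 117723951 to 117957050, with 161 intervals covering 48.5 kb. No random placement gave a cluster with more than 10000 bp of interval sequence. The number of clusters depends on the joining distance, with 32794 at 5 kb and 14585 at 25 kb.

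At the scale of megabases, H3K56ac intervals were concentrated in a limited part of the genome. Of 2590 bins of 1 Mb, the densest 259 held 42.4% of the intervals, against 18.0% (17.8% to 18.1%) in the random placements. The bins of a chromosome began with that of its first listed interval, and random intervals placed before that bin were counted in it. Such first bins were overfull in the random placements, so the random share is, if anything, too high. The bin with the most intervals was on chromosome 11 from 117000001 to 118000000, with 365 intervals covering 89.3 kb. It was followed by chromosome 11 from 97000001 to 98000000 with 344 intervals, and by the neighbouring bins of chromosome 10 from 80000001 to 81000000 with 325 and from 79000001 to 80000000 with 320. In the opposite direction, 273 bins (10.5%) held no interval, against at most 4 in a random placement. When each cluster was counted once, the densest 259 bins held 26.6% of clusters, against a mean of 18.9% and at most 19.3% in 20 random placements.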

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

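The alternatives for clusters, for bins, for median width, for X widths and for the distal ends, the density settings that use clusters, 500 bp intervals or length from position 1, and those without the sequence named 21 were chosen after the data were examined. Of 27 alternative values, 18 stayed close to the main value, 8 moved, and 1 changed direction: the mean log2 ratio of distal to other density, 0.47 with the distal 10% of the span, was -0.032 with the distal 5%, where the median ratio stayed above 1 (1.46, against 1.39) and the SD was wider (1.77, against 0.83). Counts are within 1.5 times of the main one where they stayed close. The number of intervals, 92549 as deposited, was 67860 after merging under 500 bp, 52860 after merging under 1000 bp and 38698 when only intervals wider than the median were kept, whose median width was 250 bp. The autosomal excess of density over X, 2.78-fold, ranged from 1.71 for clusters of joined intervals to 6.20 for intervals of at least 500 bp. It was 3.63 for intervals wider than the median and 2.35 after merging under 1000 bp. Joining or merging acts more where intervals are denser, which in itself tends to lower this excess. The ratio of random to observed median gap, 11.9, fell to 5.63 after merging under 500 bp, which removes short gaps by construction, and was 17.4 for intervals wider than the median. Clusters numbered 14585 at a joining distance of 25 kb against 22232 at the main distance. The share of the list in the densest 10% of 1 Mb bins, 42.4%, was 26.6% with each cluster counted once. The planned removal of unplaced contigs and chrM took out 0 intervals and tests nothing, yet it is counted among the 18. So are the settings without the sequence named 21, which holds 106 of the 92549 intervals and could change little. The settings foreseen for start sites, features, genes, gene lists, the motif, GC content and a score were not run, since no mm9 annotation or genome was used here and the list has no score. Without read counts, weak sites missed at this depth cannot be told from sites without H3K56ac.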

Other observations

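The stretches without H3K56ac intervals were long. The longest, 7.70 Mb, lay on chromosome 7 between 39039700 and 46741651, followed by 5.18 Mb on X between 25586400 and 30764001, 5.08 Mb on chromosome 18 between 85599500 and 90679751, 4.99 Mb on chromosome 17 between 57470100 and 62461401, and 4.82 Mb on chromosome 12 between 47624400 and 52448101. In 100 random placements the longest gap was at most 0.943 Mb, and 355 gaps of the list exceeded 1 Mb. Dense and sparse stretches extended over neighbouring megabases: within chromosomes, the interval counts of bins 1 Mb apart were correlated across bins (r = 0.54), as were those 2 Mb apart (0.35), while the values at 5 Mb (0.13) and 10 Mb (0.08) were lower. The random placements, binned in the same way as for the shares above, gave at most 0.05 at 1 Mb and at 5 Mb. Bins are not independent replicates, and stretches to which reads cannot be assigned were not excluded.

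The tests of low density alone, of the 300 bp gaps and of the sequence named 21 were chosen after the result was seen; the tests of neighbourhoods, of 1 copy of X and of the distal ends were written down before their own results were computed, but after the list had been examined, and none was part of the original plan.

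The X chromosome had fewer intervals than the autosomes, with a lower mean width. Matching for sparse placement reduced the difference in mean width but did not remove it. Autosomal intervals were reweighted to the numbers of neighbours within 10 kb that X intervals have. They then averaged 149 bp on the narrowest autosome, chromosome 5, and 164 ± 7.02 bp (SD, 19 autosomes). The mean on X was 137 bp (bootstrap 95% interval 131 to 143). With each number of neighbours matched on its own, a check added later because the last of the 5 classes was open-ended, the narrowest autosome averaged 145 bp and the mean was 159 ± 6.13 bp (SD, 19 autosomes). X stayed below all 19, but the narrowest (144.7 bp) lay close to the upper bootstrap limit of X (143.2 bp). Clustered intervals are not independent, which this bootstrap may not cover. Neighbours were counted from the same calls as the widths, so weaker signal on X could lower both. Matching on neighbours therefore cannot separate sparse placement from weaker signal. Low density alone stays open: X lay -4.09 residual SDs from the line of mean width on density through the 19 autosomes, but its density (13.5 per Mb) is below that of any autosome (24.2 or more), so the line is extrapolated there, and it was nearly flat (Pearson r = 0.22, permutation p = 0.37; Spearman rho = 0.14, permutation p = 0.56; r = 0.02 without the 2 autosomes farthest from the median density). E14Tg2a is a male line, and 1 copy of X under 1 calling threshold may leave less of each site, and fewer sites, above the threshold. The effect of copy number on the number of intervals was not tested. Mean width on X was below that of all 19 autosomes in 3 of 5 neighbour classes. These were the classes with 0, 2 and 6 or more neighbours. With each number matched within the last class, X (187 bp, bootstrap 95% interval 172 to 202) was still the lowest, but the interval reached past the narrowest autosome (200.3 bp). In the class with 1 neighbour X was just inside the autosomal range (115.4 bp against 115.3 to 143 bp), as in that with 3 to 5 (151 bp against 150.5 to 189 bp). Lower acetylation of X sites themselves, and poorer read assignment on X, remain open and were not tested, since the list holds neither signal nor reads.

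The excess of 300 bp gaps was not shared by the adjoining steps, as a fixed step in the windowing of the signal could give. The count at 300 bp was 1.27 times the trend of longer gaps, with 250 bp at 0.966 times. No excess recurred at 600 bp (1.00 times, 0.958 to 1.05) or at 900 bp (0.997 times, 0.936 to 1.06). The extrapolated trend also missed the counts at 150 bp (0.895 times) and 200 bp (0.795 times), so the cause of the excess is not settled. A smaller excess at 400 bp (1.04 times, 1.01 to 1.08) lay within the fitted range. The excess appeared at similar size for narrow and wide neighbours. A gap of variable length between acetylated nucleosomes would spread over the adjoining steps; the value at 350 bp, 0.991 times the trend, has a counting interval that includes the trend (0.957 to 1.03), and the trend below 400 bp is an extrapolation, so this explanation stays open.

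The sequence named 21 may be the Y chromosome under a number. Of the 21 nuclear chromosomes named in the RefSeq gene table, the list names 20, and the one without a name in it is Y. The first interval of the sequence named 21 starts at 48451, whereas those of all other chromosomes start past 3 Mb. Which sequence was meant is not given in the sources used here.

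A hypothesis that intervals are denser toward the distal end of the autosomes, away from the centromere, received limited support. The distal 10% of the span was denser than the rest on 14 of 19 autosomes (median ratio 1.39, mean log2 ratio 0.47 ± 0.83 (SD, 19 autosomes), exact two-sided sign-flip permutation p = 0.025), from 3.25-fold on chromosome 15 to 0.510-fold on chromosome 18. The result depended on the length chosen: with the distal 20% it was 13 of 19 (p = 0.019, exact), and with the distal 5% it was 12 of 19, with a median ratio of 1.46 but a mean log2 ratio of -0.032 ± 1.77 (SD; p = 0.94, exact). The mean at 5% was lowered most by chromosomes 17 (ratio 0.077) and 18 (0.045), and without chromosome 18 it was 0.22 (p = 0.54, exact). At 10%, leaving out each autosome in turn gave exact p-values from 0.0091 to 0.048. With each cluster counted once, 15 of 19 autosomes were denser in the distal 10% (p = 0.0061, exact). The other lengths and the clusters were added after the first result, and the 4 p-values were not adjusted for one another.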
